A study of Rattus norvegicus with 23 samples.

How the data were processed

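Kidney RNA of 23 male rats was hybridised to Affymetrix arrays, 1 array per sample, in 4 groups of strain (SBN/y or SBH/y) and kidney number. The deposited values are on a log2 scale, 1 value per probe set and array, and the authors made them with GCOS and RMA, per the submitters' processing notes, which give no version. RMA is known to correct background, to quantile-normalize the arrays and to summarise the probes of a probe set. The values ran from 1.89 to 13.67, with array medians between 4.64 and 4.69. Normalization of this kind gives every array nearly the same distribution, so a change in the total amount of mRNA could not be seen. No scan date was known, so batches of arrays could not be examined. The labels do not say more about separate animals than the sample names do, so p-values measure the spread between these samples.

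Of 31099 probe sets, 57 controls were left out of the tests and 31042 were tested. A table of the array's annotation gave exactly 1 gene symbol for 20826 of these, several for 436 and none for 9780, and only those with 1 symbol were named. For 20758 the gene identifier was found in the RefSeq annotation of the GRCr8 assembly, which served only for names and for the order of neighbouring genes. A gene was represented by its probe set with the highest mean over all arrays, which gave 14217 genes. No column of values was left unused.

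All comparisons came from 1 limma fit (limma 3.58.1, R 4.3.3) with a mean for each of 4 groups and no further normalization. The contrasts were SBH/y minus SBN/y with 2 kidneys and with 1, 1 kidney minus 2 kidneys in each strain, the difference between these responses, and both effects on average. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets of a contrast, with a threshold of 0.05. Errors beside log2 differences are standard errors of the fit unless SD is given or another kind of error is named. Before the data were examined, the contrasts, 34 gene lists and the rule for naming genes were fixed. The rule took the 12 genes with the largest increase and the 12 with the largest decrease past the threshold in each contrast (8 each for the interaction), leaving out bare locus symbols, and up to 4 genes with the smallest p from each list. Uncharacterised loci were thus counted but not named.

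The lists held 543 entries, of which 487 were measured. Each was tested with camera in limma, with a preset correlation of 0.01 between genes, and adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run as alternatives. Some genes belong to more than 1 list, so the lists are not independent. The gene Cd74, for example, belongs to both the myeloid and the antigen presentation list. Scnn1a, Scnn1b, Scnn1g and Hsd11b2 belong to both the principal cell and the sodium transport list. Camera called 7, 14, 11, 22 and 16 lists for strain with 2 kidneys, strain with 1, uninephrectomy in SBN/y, in SBH/y and the interaction, and 0, 0, 3, 12 and 4 with an estimated correlation.

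The fit was tested on simulated data with 200 probe sets changed in SBH/y after uninephrectomy, over 31042 probe sets. It recovered 94 of 100 changed by 0.5 log2 and 99 of 100 changed by 1 log2, with 8 false calls. Of 40 simulated lists, camera called the 10 that were shifted by 0.3 log2 and 0 others, over 14217 genes. The noise was drawn independently for each probe set, so the genes of these lists were not correlated. In the real data the estimated correlation was 0.386 for antigen presentation genes, for example. The simulation therefore does not show how often the preset correlation gives false list calls in the real data.

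The alternatives tried were a repeated quantile normalization, a filter on dim probe sets, a trended and robust variance, fits with only the groups compared, 1 probe set per gene, the next probe set of a gene, the replicate number as a block, and each array left out in turn. A GAPDH covariate and a fit without 3 arrays were added after the data had been examined. Each comparison was repeated on 100 splits of the samples, the real one included.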

Results

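Gene expression was measured in the kidneys of 23 male rats on Affymetrix arrays carrying 31099 probe sets. The rats belonged to a pair of strains, SBN/y and SBH/y, which are known as the hypertension-resistant and the hypertension-prone line of the Sabra rat. In each strain, 1 group kept both kidneys after a sham operation (5 SBN/y and 6 SBH/y rats) and 1 group lost 1 kidney by uninephrectomy (6 SBN/y and 6 SBH/y rats). The kidneys were taken at 4 months of age, 3 months after surgery. The title of the series names proteinuria as its subject. The design therefore asks how the kidney of each strain differed 3 months after the loss of the other kidney, how the strains differed with 2 kidneys and with 1, and whether the uninephrectomy response differed between the strains. Each array stood for 1 labelled kidney sample, and the number of arrays set the precision of every comparison.

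The first principal component held 34.7% of the variance and parted the strains. It also parted the arrays by kidney number within both strains. SBN/y arrays lay between -21.3 and -20.5 on it with 2 kidneys and between -17.6 and -15.8 with 1, and SBH/y arrays between 11.3 and 13.3 with 2 and between 18.6 and 26.8 with 1. The second component, with 13.4%, ran from -30.6 in replicate 3 of SBH/y with 2 kidneys, whose values had an SD of 1.99 over probe sets, to 28.1 in replicate 2 of SBH/y with 1 kidney, with an SD of 2.10. Correlations between arrays of 1 group lay between 0.990 and 0.997. The signal of the GAPDH control probes at the 3' end minus that at the 5' end, a sign of RNA quality, was 0.35 ± 0.03 log2 (SD, n = 5) in SBN/y with 2 kidneys. It was 0.45 ± 0.04 (SD, n = 6) in SBN/y with 1 kidney, 0.46 ± 0.06 (SD, n = 6) in SBH/y with 2 kidneys and 0.53 ± 0.11 (SD, n = 6) in SBH/y with 1 kidney, so this measure moved with the groups. Eif2s3y, which lies on the Y chromosome, was read between 7.19 and 8.06 on all 23 arrays, while the 4 probe sets of Xist stayed between 2.14 and 3.13.

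**Figure D1:**
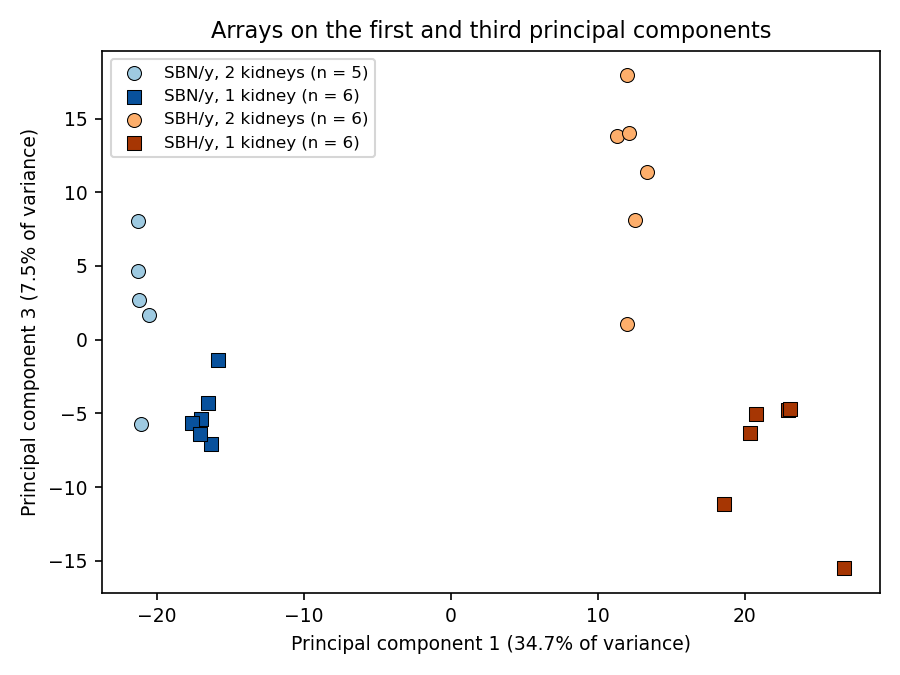
Each point is 1 array, placed by principal component 1 (34.7% of the variance) and component 3 (7.5%), both without units, with colour and shape for the 4 groups. SBN/y arrays lie at -15.8 or below on component 1 and SBH/y arrays at 11.3 or above, and in both strains the arrays with 1 kidney lie to the right of those with 2.

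In SBH/y kidneys, genes of tubular injury, matrix and immune cells rose after uninephrectomy. Havcr1, the injury marker of the proximal tubule also known as Kim-1, rose most, by 3.20 ± 0.24 (SE) on the log2 scale, from 4.21 ± 0.29 (SD, n = 6) to 7.42 ± 0.63 (SD, n = 6). The starting level lay under that of the median probe set (4.662), where background can make a difference look smaller than it is. Spp1, which encodes osteopontin, rose by 1.45 ± 0.10 (SE) to 12.01 ± 0.30 (SD, n = 6). Cyp1a1, a xenobiotic-metabolising P450 (-1.94 ± 0.21, SE), the kallikrein-related Klk1c4 (-1.85 ± 0.21) and Cyp2c11, known as the male-specific P450 of rat liver (-1.57 ± 0.16), fell most. Of 31042 probe sets tested, 1563 changed at an adjusted p under 0.05 with limma, 950 upwards and 613 downwards, and they covered 1138 genes. At least 2-fold changes were found at 32 probe sets upwards and 3 downwards.

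Gpnmb, a glycoprotein of activated macrophages (1.76 ± 0.14, SE), Mmp12, the macrophage elastase (1.45 ± 0.13), and Jchain, which joins secreted IgA and IgM (1.65 ± 0.20), rose, as did the immunoglobulin gene Ighl2 (1.38 ± 0.16). Also among the 12 genes with the largest increases were Tnfrsf12a, the receptor of TWEAK (1.40 ± 0.12), the metalloproteinase gene Adamts1 (1.36 ± 0.19), the ubiquitin-like Ubd (1.35 ± 0.10), Clu (1.25 ± 0.12), Ccn1 (1.24 ± 0.13) and the protease inhibitor gene Slpi (1.13 ± 0.10). A second, dimmer probe set of Clu differed by 0.18 (adjusted p = 0.214). Downwards, Nr1d1, a repressor of the circadian clock, fell by 0.90 ± 0.17, Pou3f1 by 0.88 ± 0.13, Cacng5 by 0.81 ± 0.11, the water channel gene Aqp4 by 0.67 ± 0.15 and Dnase1 by 0.67 ± 0.10. Acadsb, an enzyme of branched-chain acyl-CoA oxidation (-0.80 ± 0.17), Slc22a13, an organic anion transporter (-0.69 ± 0.14), Clic3 (-0.70 ± 0.11) and Tesc (-0.69 ± 0.09) completed the list. The groups overlapped for Nr1d1, Cacng5, Acadsb, Slc22a13 and Aqp4.

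Of 22 measured genes of extracellular matrix and fibrosis, 17 rose in SBH/y (17 adjusted over the list alone). Among them were Col3a1 (0.72 ± 0.09), Fbn1 (0.67 ± 0.08), Col5a2 (0.77 ± 0.11) and Col6a1 (0.56 ± 0.08). The list shifted upwards with a camera adjusted p = 5.22e-19, and adjusted p = 0.00879 with an estimated correlation. Of 19 tubular injury genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Timp1 at 0.95 ± 0.10 and Clu at 1.25 ± 0.12 (camera adjusted p = 3.63e-13; adjusted p = 0.00879 with an estimated correlation). Myeloid cell markers rose for 12 of 16 genes (12 adjusted over the list alone), including Cd68 (0.67 ± 0.09), Laptm5 (0.54 ± 0.07), Csf1r (0.45 ± 0.07) and Lyz2 (0.46 ± 0.08), at adjusted p = 0.0143 with an estimated correlation. Lymphocyte markers rose for 4 of 10 genes (7 adjusted over the list alone), led by Cd3g (0.62 ± 0.08) and Cd3e (0.46 ± 0.08), at adjusted p = 0.0143 with an estimated correlation. Antigen presentation genes rose for 9 of 18 (17 adjusted over the list alone), with RT1-DMa at 0.54 ± 0.08 and Psmb8 at 0.60 ± 0.09, at adjusted p = 0.0167 with an estimated correlation. Cell cycle genes rose for 6 of 19 (12 adjusted over the list alone; adjusted p = 0.0115 with an estimated correlation), led by Mki67 (0.48 ± 0.09) and Ccnb2 (0.45 ± 0.10). Mki67 was dim, read at 3.24 to 3.51 in SBN/y with 1 kidney, under the median probe set (4.662), so the size of its rise is uncertain. Immediate early genes rose for 7 of 13 (7 adjusted over the list alone; adjusted p = 0.0226 with an estimated correlation), with Klf6 at 0.95 ± 0.10 and Atf3 at 0.60 ± 0.10.

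Intercalated cell, principal cell and renin-angiotensin genes went the other way in SBH/y. Intercalated cell genes fell for 5 of 8 (8 adjusted over the list alone; adjusted p = 0.0143 with an estimated correlation), including the anion exchanger gene Slc4a1 (-0.43 ± 0.06) and the ammonia transporter gene Rhcg (-0.37 ± 0.06). Principal cell genes fell for 2 of 10, Aqp4 and Fxyd4 (-0.38 ± 0.10), and for 7 adjusted over the list alone (adjusted p = 0.0226 with an estimated correlation). Renin-angiotensin genes fell for 4 of 12 (6 adjusted over the list alone; adjusted p = 0.00879 with an estimated correlation): Mme (-0.37 ± 0.07), which encodes neprilysin, Anpep (-0.20 ± 0.05) and the angiotensin receptor genes Agtr1a (-0.24 ± 0.06) and Agtr1b (-0.41 ± 0.11). Sodium transport genes fell for 3 of 17 (8 adjusted over the list alone; adjusted p = 0.0409 with an estimated correlation), led by the exchanger gene Slc9a3 (-0.49 ± 0.08). Endothelial genes fell for 2 of 11 (3 adjusted over the list alone; adjusted p = 0.0167 with an estimated correlation), Emcn (-0.31 ± 0.05) and Kdr (-0.26 ± 0.06). Podocyte genes fell for 4 of 15 (6 adjusted over the list alone), namely Ptpro (-0.42 ± 0.07), Vegfa (-0.25 ± 0.05), the nephrin gene Nphs1 (-0.42 ± 0.09) and Wt1 (-0.36 ± 0.09), with camera adjusted p = 9.66e-05 but adjusted p = 0.0777 with an estimated correlation. The samples were whole kidneys, so a change per cell and a change in the share of a cell type were not separated, and the GAPDH measure of RNA quality was 0.53 against 0.46 log2 in the same groups. In all, 22 of 34 lists passed camera, of which 12 also passed with an estimated correlation.

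**Figure D2:**
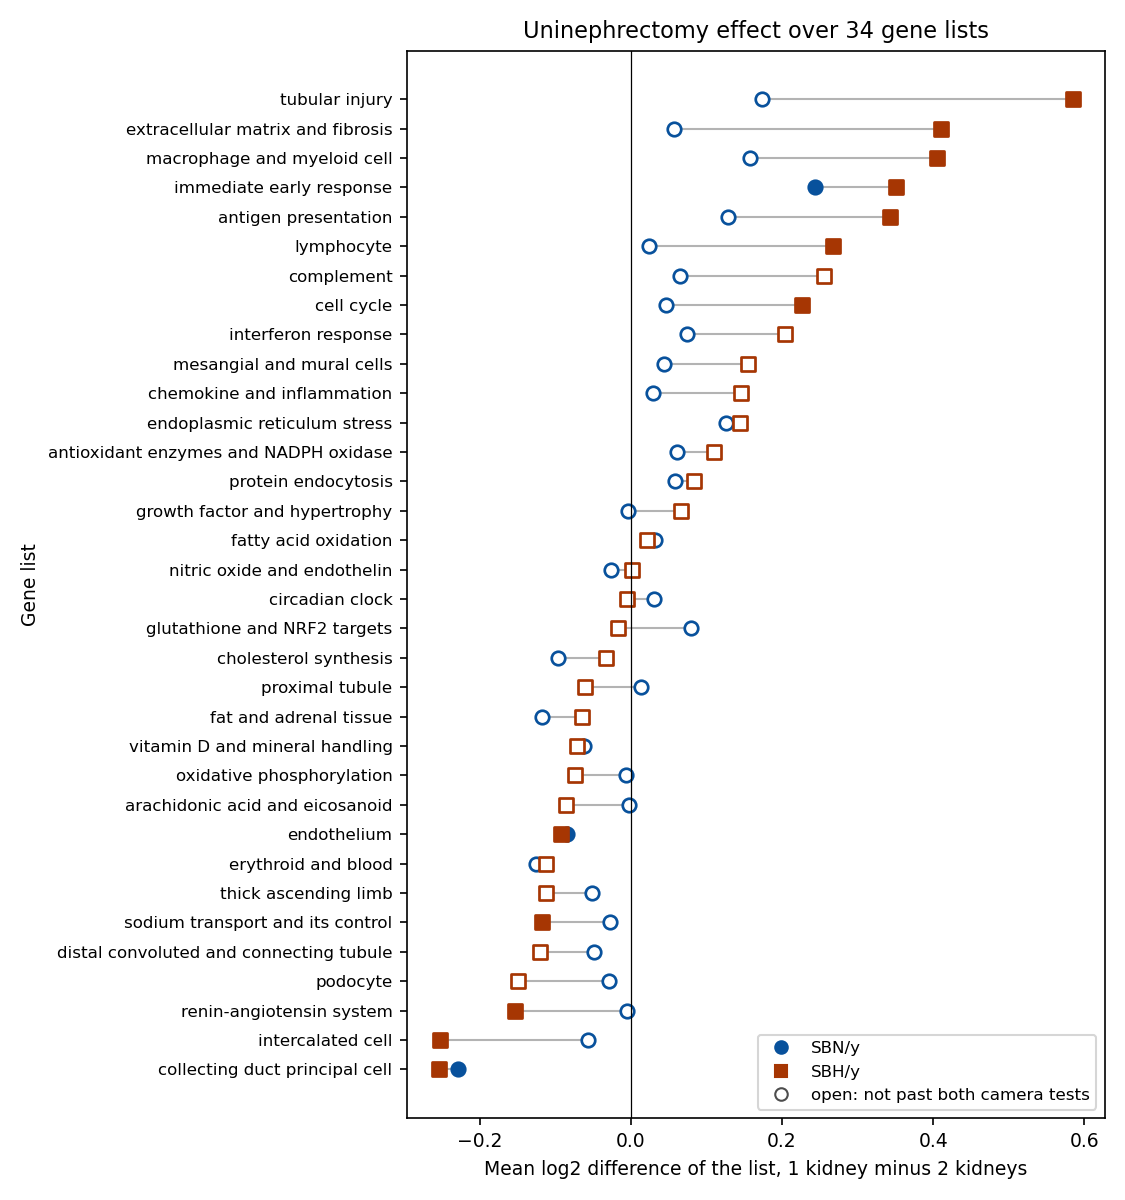
Each row is 1 of 34 gene lists, and points give the mean log2 difference of its genes, 1 kidney minus 2 kidneys, in SBN/y (circles) and SBH/y (squares); filled points passed camera with the preset and with the estimated correlation. The tubular injury list lies at 0.59 in SBH/y and 0.17 in SBN/y, and the matrix list at 0.41 and 0.06.

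In SBN/y kidneys, uninephrectomy changed few genes at this threshold, again with Havcr1 in the lead. Havcr1 rose by 1.37 ± 0.25 (SE) log2, again from a level under that of the median probe set, 3.86 ± 0.10 (SD, n = 5), to 5.23 ± 0.60 (SD, n = 6). Slc25a25, a mitochondrial ATP-Mg/phosphate carrier gene, rose by 1.31 ± 0.22, Ubd by 0.80 ± 0.10 and the calcineurin regulator gene Rcan1 by 0.69 ± 0.10. Nkd2, a Wnt antagonist gene (-0.75 ± 0.12), the aldose reductase gene Akr1b1 (-0.68 ± 0.11) and the uroguanylin gene Guca2b (-0.47 ± 0.08) fell. With limma, 52 probe sets passed, 26 in each direction, covering 39 genes, and 2364 had an unadjusted p under 0.05.

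The other genes named in SBN/y changed by less. Sfpq rose by 0.54 ± 0.09, Manf, an endoplasmic reticulum stress protein gene, by 0.52 ± 0.08, and Tgif1 by 0.48 ± 0.08. Cys1 (0.59 ± 0.12), Tmem252 (0.57 ± 0.11), the heme oxygenase gene Hmox1 (0.56 ± 0.11), the AP-1 gene Jun (0.53 ± 0.11) and P4ha1 (0.46 ± 0.09) also passed upwards, and Pamr1 (-0.46 ± 0.08), Herc3 (-0.42 ± 0.08), the taurine transporter gene Slc6a6 (-0.42 ± 0.09), Spp2 (-0.39 ± 0.07), Prox1 (-0.35 ± 0.07), Srsf5 (-0.34 ± 0.07) and Bmp4 (-0.30 ± 0.06) downwards. Dgkg (-0.33 ± 0.07) and Zfp658l1 (-0.32 ± 0.07) passed as well. The groups overlapped for P4ha1, Akr1b1, Slc6a6 and Srsf5. Second probe sets did not pass for any of the 6 genes that had one. They moved the same way for Jun (0.605, adjusted p = 0.151), Slc6a6 (-0.53, adjusted p = 0.0651) and Dgkg (-0.43, adjusted p = 0.133), and were dimmer and nearer 0 for Akr1b1 (-0.07), Herc3 (-0.14) and Prox1 (0.05).

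As groups, immediate early genes, principal cell genes and endothelial genes shifted in SBN/y, although 1 of their members passed over all probe sets. Immediate early genes moved upwards (mean 0.24, camera adjusted p = 1.6e-07; adjusted p = 0.0359 with an estimated correlation), with Jun past the test, 7 of 13 past it adjusted over the list alone, and Egr1 at 0.74 ± 0.17. Principal cell genes moved downwards (mean -0.23; adjusted p = 0.0337 with an estimated correlation), with 5 of 10 past the test adjusted over the list alone and Fxyd4 at -0.41 ± 0.11 and Aqp2 at -0.37 ± 0.12. Endothelial genes moved downwards by a mean of -0.08 (adjusted p = 0.0337 with an estimated correlation), with Emcn at -0.20 ± 0.05, past the test adjusted over the list alone. Tubular injury genes had a mean of 0.17, with 1 of 19 past the test (5 higher and 1 lower adjusted over the list alone), and myeloid markers a mean of 0.16, with 0 of 16 past it, with adjusted p = 0.382 and adjusted p = 0.239, respectively, with an estimated correlation. The count of 52 fell to 24 without replicate 3 of either SBN/y group, to 25, 34 and 32 without replicates 4, 2 and 1 of SBN/y with 2 kidneys, and to 26 without replicate 1 of SBN/y with 1 kidney. Leaving out 1 array ended the call of 14 of the 24 named genes, with adjusted p up to 0.160, but not of Havcr1, Slc25a25, Ubd, Rcan1, Sfpq, Manf, Tgif1, Nkd2, Akr1b1 or Guca2b. With the GAPDH measure as a covariate, 62 probe sets passed, of which 17 lay higher and 45 lower. Only 31 of the 52 calls made without the covariate were among them.

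**Figure D3:**
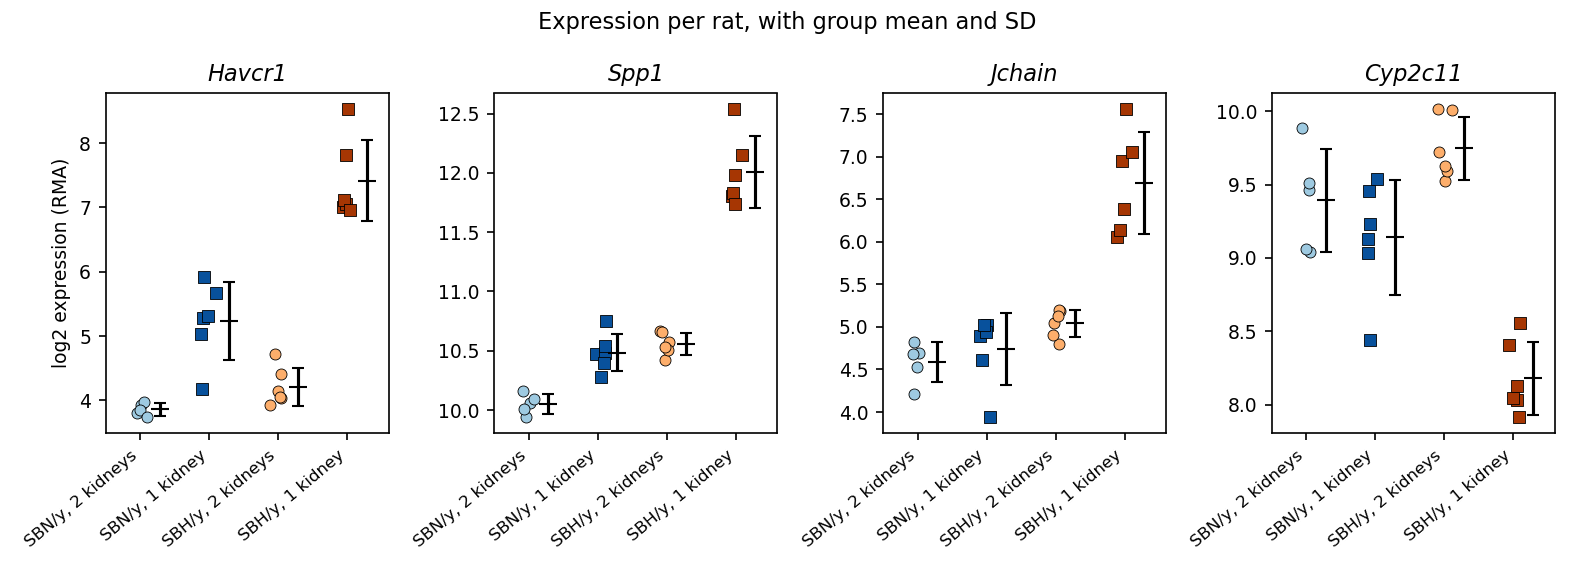
Points give the log2 expression of Havcr1, Spp1, Jchain and Cyp2c11 in each rat of the 4 groups, and bars beside them the group mean and SD. Havcr1 averages 7.42 in SBH/y with 1 kidney against 5.23 in SBN/y with 1 kidney, and Cyp2c11 averages 8.18 against 9.14.

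The uninephrectomy response differed between the strains at 79 probe sets covering 61 genes (limma interaction). The response in SBH/y was more positive at 65 and more negative at 14. Havcr1 led with a difference of 1.83 ± 0.34 (SE) between the responses, followed by Jchain, Mmp12 (1.31 ± 0.19), Ighl2 (1.29 ± 0.23) and Gpnmb (1.27 ± 0.20). Tnfrsf12a (1.12 ± 0.17) and Spp1 (1.01 ± 0.14) came next. The oxidised LDL receptor gene Olr1 passed too, but was read at 2.61, 2.63 and 2.77 in the groups other than SBH/y with 1 kidney (3.78), within the range of the Xist probe sets in these males, so the size of its difference was not measured. Cyp2c11 (-1.31 ± 0.23), Nr1d1 (-1.12 ± 0.24), Pou3f1 (-1.06 ± 0.19), the glucuronosyltransferase gene Ugt2b7 (-0.87 ± 0.16) and Eri2 (-0.80 ± 0.11) led the other direction, with Pim3 (-0.70 ± 0.10) and the acyl-CoA synthetase gene Acsm3 (-0.62 ± 0.10). Serpinb12 passed in that direction as well, without a measured size, since SBN/y with 2 kidneys was read at 3.01, in the Xist range.

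Jchain stood at 4.59 ± 0.23 (SD, n = 5) and 4.74 ± 0.42 (SD, n = 6) in SBN/y with 2 kidneys and with 1, and at 5.04 ± 0.16 and 6.69 ± 0.59 (SD, n = 6 each) in SBH/y. Its second, dimmer probe set gave an interaction of 0.42 (adjusted p = 0.297). Mmp12 stood at 4.17 ± 0.14 (SD, n = 5) and 4.32 ± 0.14 (SD, n = 6) in SBN/y against 4.79 ± 0.18 and 6.24 ± 0.43 (SD, n = 6 each) in SBH/y. Ugt2b7 went from 6.40 to 6.80 in SBN/y and from 7.31 to 6.84 in SBH/y, and Pim3 from 8.07 to 8.30 and from 8.38 to 7.90. A second probe set of Eri2 gave -0.38 (adjusted p = 0.544 from limma).

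Tubular injury genes responded more in SBH/y for 8 of 19 (10 adjusted over the list alone), including Spp1, Clu (0.99 ± 0.17), Timp1 (0.86 ± 0.15) and Vim (0.63 ± 0.12), at adjusted p = 0.0177 with an estimated correlation. Matrix genes did so for 2 of 22, Fbn1 (0.65 ± 0.12) and Mmp2 (0.55 ± 0.11), and for 15 adjusted over the list alone, at a mean of 0.35 and adjusted p = 0.0177 with an estimated correlation. Lymphocyte markers shifted upwards with 1 of 10 past the test, Cd3g at 0.67 ± 0.11 (3 adjusted over the list alone; adjusted p = 0.0397 with an estimated correlation). Renin-angiotensin genes shifted downwards with 1 of 12 past the test, Mme at -0.44 ± 0.10 (2 adjusted over the list alone; adjusted p = 0.0177 with an estimated correlation). Camera called 12 further lists whose call was lost that way, among them myeloid markers (mean 0.25, 0 of 16 past the test, 8 adjusted over the list alone; adjusted p = 0.147 with an estimated correlation) and intercalated cell genes (mean -0.20, 0 of 8 past the test, 3 adjusted over the list alone; adjusted p = 0.0592 with an estimated correlation). The count of 79 became 52 without replicate 6 of SBN/y with 1 kidney, 131 without its replicate 4, and 133 and 157 without replicates 5 and 3 of SBH/y with 1 kidney, while with the GAPDH covariate or with a trended and robust variance it was 124 each. Nr1d1 lost its call in 17 of 23 fits with 1 array left out, with adjusted p up to 0.0932.

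The 2 responses shared 30 called probe sets, 15 higher and 15 lower in both strains, where independent lists would share 0.8 and 0.5. Of the 1563 probe sets called in SBH/y, 1267 (81.1%) moved in the same direction in SBN/y, and for 1528 the difference was larger in SBH/y, the strain in which they were selected. Over all probe sets the responses correlated with a Pearson r of 0.324 and a Spearman rho of 0.226, across probe sets, which are not independent replicates. Shared genes included Havcr1, Ubd, Rcan1 and Tgif1 upwards and Pamr1 and Bmp4 downwards. No array belonged to both responses.

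With 2 kidneys in place, the strains differed most at Scd, RT1-Bb, Matn1, Krt19 and Cyp4a1. Cyp4a1, a fatty acid omega-hydroxylase gene, was 2.42 ± 0.12 (SE) log2 higher in SBH/y, at 10.33 against 7.92, and Lpl, which encodes lipoprotein lipase, was 1.58 ± 0.08 higher. Scd, the stearoyl-CoA desaturase gene, was lower by -3.00 ± 0.40, at 4.15 ± 0.16 (SD, n = 6) against 7.15 ± 1.03 (SD, n = 5), and Krt19, a keratin of duct epithelium, by -2.51 ± 0.11. Of 31042 probe sets, 2817 differed with limma, 1342 higher and 1475 lower in SBH/y, covering 1800 genes. Of these, 82 were at least 2-fold higher and 113 at least 2-fold lower.

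Other genes far higher in SBH/y were Sdf2l1, a chaperone cofactor of the endoplasmic reticulum (2.23 ± 0.11), the peroxisomal membrane protein gene Pxmp4 (2.04 ± 0.11), the ubiquitin ligase gene Rnf6 (2.01 ± 0.13), Vps13c (1.80 ± 0.13), Gadl1 (1.74 ± 0.12), Cyp1a1 (1.65 ± 0.22), Ube3al1 (1.46 ± 0.10) and the biliverdin reductase gene Blvra (1.44 ± 0.09). Mis18a was higher as well, at 4.92 against 3.12 in SBN/y, a level in the Xist range, so the size of the difference was not measured. The matrilin gene Matn1 was lower by -2.61 ± 0.13. Far lower as well were the carboxylesterase gene Ces1e (-2.38 ± 0.11), Mpv17l (-2.25 ± 0.13), Dph6 (-2.13 ± 0.12), Mrap, which encodes an accessory protein of the ACTH receptor (-2.03 ± 0.12), Pou2f1 (-1.81 ± 0.12) and Ly6i (-1.80 ± 0.07). Thrsp, which is known for its part in lipogenesis (-1.78 ± 0.32), and Ucp1, the uncoupling protein of brown fat (-1.77 ± 0.36), were lower too, with groups that overlapped. Of the fat and adrenal list, Fabp4 (-0.83 ± 0.23) and Adipoq (-0.31 ± 0.08) were lower as well, 2 of 9 genes (2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.323; adjusted p = 0.699 with an estimated correlation). Scd, Thrsp and Ucp1 varied widely in SBN/y with 2 kidneys, with SDs of 1.035, 0.877 and 0.998. For these genes, a different share of fat tissue in the samples was not told apart from a change in kidney cells. The class II histocompatibility genes RT1-Ba (2.20 ± 0.09) and RT1-Bb (-2.66 ± 0.15) passed in opposite directions. A second probe set of RT1-Ba was lower by -0.48 (adjusted p = 0.00444) and that of RT1-Bb differed by 0.05 (adjusted p = 0.821), so both directions held for single probe sets of polymorphic genes.

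Interferon response genes were higher in SBH/y for 7 of 18 (13 adjusted over the list alone), including Ifi27 (1.24 ± 0.07), Oas1a (0.38 ± 0.09), Ifit3 (0.40 ± 0.10) and Irf7 (0.44 ± 0.11), with camera adjusted p = 1.96e-07 and adjusted p = 0.551 with an estimated correlation. Antigen presentation genes were higher for 9 of 18 and lower for 1 (10 and 1 adjusted over the list alone; adjusted p = 0.551 with an estimated correlation). RT1-Db1 (1.16 ± 0.09) and RT1-Da (0.72 ± 0.09) were among those higher. Myeloid markers were higher for 5 of 16 and lower for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.586 with an estimated correlation), with Lyz2 at 0.78 ± 0.08 and Mrc1 at -0.65 ± 0.14. Matrix genes were higher for 6 of 22 and lower for 1 (8 and 2 adjusted over the list alone; adjusted p = 0.586 with an estimated correlation), with Ccn2 at 0.62 ± 0.11, Col4a2 at 0.59 ± 0.09 and Mmp2 at -0.53 ± 0.08. Tubular injury genes were higher for 4 of 19, including Lgals3 (0.76 ± 0.09) and Spp1 (0.51 ± 0.10), and lower for 1, Krt19 (4 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.106; adjusted p = 0.586 with an estimated correlation). Genes of red blood cells, Alas2 (-0.81 ± 0.15), Hba-a3 (-0.75 ± 0.16) and Hbb (-0.53 ± 0.14), were lower, 3 of 5 measured (3 adjusted over the list alone; adjusted p = 0.551 with an estimated correlation). Cholesterol synthesis genes were lower for 4 of 14 (4 adjusted over the list alone; adjusted p = 0.551 with an estimated correlation), led by Idi1 (-0.79 ± 0.14). Immediate early genes were higher for 3 of 13 (5 adjusted over the list alone; adjusted p = 0.551 with an estimated correlation), with Jun at 0.54 ± 0.11.

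Clock genes differed in both directions, 4 of 16 higher and 7 lower in SBH/y (6 and 8 adjusted over the list alone), so that camera did not call the list (adjusted p = 0.0861) while fry found change in either direction (adjusted p = 3.82e-09). That fry test was not particular to clock genes. It also passed other lists that camera did not call, such as glutathione genes (fry adjusted p = 5.74e-19) and tubular injury genes (fry adjusted p = 1.89e-17). Dbp (-1.75 ± 0.14) and Per3 (-1.11 ± 0.15) were lower, and Bmal1 (1.07 ± 0.13) and Nfil3 (0.83 ± 0.11) higher. The arachidonic acid list split in the same manner, 5 of 18 higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.291), with Cyp4a8 at 1.16 ± 0.06, Cyp4a3 at -1.19 ± 0.09 and the soluble epoxide hydrolase gene Ephx2 at -0.79 ± 0.07. The Cyp4a genes are close paralogs, and whether their probes tell them apart was not tested. None of the 7 lists called with 2 kidneys was called with an estimated correlation. With 1 probe set per gene, 1748 of 14217 genes passed.

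After uninephrectomy the strains differed at 4342 probe sets covering 2792 genes, 2345 higher and 1997 lower in SBH/y. Havcr1 was 2.18 ± 0.24 (SE) log2 higher in SBH/y, Jchain 1.95 ± 0.20, Mmp12 1.93 ± 0.13, the chemokine gene Ccl6 1.78 ± 0.12 and Gpnmb 1.74 ± 0.14. Of these, Ccl6, Mmp12 and Gpnmb were already higher in SBH/y with 2 kidneys, while Havcr1 and Jchain did not pass there. Of the genes already named with 2 kidneys, RT1-Ba (2.54 ± 0.09), Sdf2l1 (2.46 ± 0.11), Cyp4a1 (2.43 ± 0.12), Pxmp4 (2.39 ± 0.11), Rnf6 (2.19 ± 0.12) and Vps13c (1.70 ± 0.12) were again among the 12 highest. Mis18a was higher again, without a measured size, at 5.06 against 3.02 in SBN/y, in the Xist range. Ces1e (-2.70 ± 0.11), Mpv17l (-2.66 ± 0.12), RT1-Bb (-2.53 ± 0.14), Matn1 (-2.24 ± 0.12), Mrap (-2.23 ± 0.11), Dph6 (-2.12 ± 0.11), Ly6i (-2.11 ± 0.07) and Krt19 (-2.04 ± 0.11) were again among the 12 lowest. Nr1d1 (-2.15 ± 0.17), Dbp (-2.03 ± 0.13), Bhmt, which remethylates homocysteine (-2.01 ± 0.08), and the aldehyde dehydrogenase gene Aldh1b1 were the other 4. The second probe set of RT1-Ba was again lower, by -0.73 (adjusted p = 1.27e-05), with that of RT1-Bb at -0.07 (adjusted p = 0.646).

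Matrix genes were higher in SBH/y after uninephrectomy for 17 of 22 (17 adjusted over the list alone), with Col6a1 at 0.87 ± 0.08, Col6a3 at 0.62 ± 0.06, Col4a1 at 0.69 ± 0.07 and Lox at 0.96 ± 0.10 (camera adjusted p = 2.47e-13; adjusted p = 0.0852 with an estimated correlation). Tubular injury genes were higher for 13 of 19 and lower for 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0852 with an estimated correlation), with Spp1 at 1.52 ± 0.10, Lgals3 at 1.29 ± 0.08 and Timp1 at 1.19 ± 0.10. Interferon genes were higher for 15 of 18 (15 adjusted over the list alone; adjusted p = 0.094 with an estimated correlation), with Ifi27 at 1.60 ± 0.07 and Isg15 at 0.77 ± 0.09. Antigen presentation genes were higher for 14 of 18 and lower for 1 (16 and 1 adjusted over the list alone; adjusted p = 0.094 with an estimated correlation). Myeloid markers were higher for 11 of 16 and lower for 1 (11 and 1 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), with Lyz2 at 1.02 ± 0.08 and Cd68 at 0.83 ± 0.09. Cell cycle genes were higher for 10 of 19 (10 adjusted over the list alone; adjusted p = 0.094 with an estimated correlation). Mki67 was higher by 0.46 ± 0.09, but SBN/y was read at 3.24 to 3.51, close above the Xist range, so this size is uncertain. Complement genes were higher for 5 of 9 and lower for 2 (6 and 2 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation), with Cfi at 1.13 ± 0.13. Intercalated cell genes were lower for 5 of 8 (5 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation), led by Slc4a1 (-0.35 ± 0.06). Genes of the thick ascending limb were lower for 4 of 8 (4 adjusted over the list alone; adjusted p = 0.211 with an estimated correlation), among them Cldn16 (-0.46 ± 0.07) and Egf (-0.22 ± 0.06). Podocyte genes were lower for 3 of 15 (5 adjusted over the list alone; adjusted p = 0.272 with an estimated correlation), namely Vegfa (-0.27 ± 0.05), Tcf21 (-0.29 ± 0.07) and Ptpro (-0.22 ± 0.07). Camera called 14 lists here and 0 with an estimated correlation, and with 1 probe set per gene 2810 genes passed.

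The strain differences with 2 kidneys and with 1 shared 1982 called probe sets. Of these, 962 were higher and 1013 lower in SBH/y both times, where independent lists would share 101.4 and 94.9, and 7 went opposite ways. The differences correlated over all probe sets with a Pearson r of 0.782 and a Spearman rho of 0.499, again across probe sets. Averaged over kidney number, 5763 probe sets differed between the strains, 2899 higher and 2864 lower in SBH/y, with Cyp4a1 (2.42 ± 0.08) highest and RT1-Bb (-2.60 ± 0.10) lowest among the genes. Ifi27 (1.42 ± 0.05), Ccl6 (1.46 ± 0.09), Bhmt (-1.78 ± 0.06) and Aldh1b1 (-1.83 ± 0.08) were among the 24 genes named for that average. With 1 probe set per gene, 3584 genes passed.

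Averaged over the strains, uninephrectomy changed 1404 probe sets, 821 upwards and 583 downwards. Havcr1 (2.29 ± 0.17), Gpnmb (1.13 ± 0.10), Ubd (1.07 ± 0.07) and Adamts1 (0.98 ± 0.14) rose most, and Egr1, an immediate early gene, rose by 0.77 ± 0.12. Klk1c4 (-1.32 ± 0.15), Cyp1a1 (-1.27 ± 0.15), Cyp2c11 (-0.91 ± 0.11) and Cacng5 (-0.65 ± 0.08) fell most, and Gc, the vitamin D-binding protein gene, fell by 0.50 ± 0.08. Principal cell genes fell for 5 of 10 on this average (9 adjusted over the list alone; adjusted p = 0.0125 with an estimated correlation), and endoplasmic reticulum stress genes rose for 5 of 17 (12 adjusted over the list alone; adjusted p = 0.0451 with an estimated correlation). With the GAPDH measure as a covariate, the count was 804, of which 401 were upwards and 403 downwards. Of the 1404 calls made without the covariate, 646 were among them.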

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

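The tests of second probe sets, of myeloid genes, of dilution, of single rats and of the time of day were chosen only after the result was seen, and the GAPDH covariate was added after the data had been examined. For 24 of the genes named here, the uninephrectomy response differed between the strains in limma's interaction test. It was more positive in SBH/y for Havcr1 (1.83 log2), Jchain (1.497), Mmp12 (1.31), Ighl2 (1.29), Gpnmb (1.27), Tnfrsf12a (1.12), Spp1 (1.01), Clu (0.99), Slpi (0.87), Timp1 (0.86), Cd3g (0.67), Fbn1 (0.65), Vim (0.63), Mmp2 (0.55) and Olr1. It was more negative for Cyp2c11 (-1.31), Nr1d1 (-1.12), Pou3f1 (-1.06), Ugt2b7 (-0.87), Eri2 (-0.80), Pim3 (-0.70), Acsm3 (-0.62), Mme (-0.44) and Serpinb12. Some groups of Olr1 and Serpinb12 were read in the range of Xist, so the fitted values of 1.0008 and -0.66 do not give the size of their difference.

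In 1 of 100 splits of the rats, the real one, as many calls were made in each comparison. This argues against chance in their grouping for all but the interaction and uninephrectomy in SBN/y. For uninephrectomy in SBN/y, 52 calls stood against 51 in the highest other split and 24 without replicate 3 of either SBN/y group, so chance was not taken as excluded. The real count and the highest other were 2817 and 1836 for strain with 2 kidneys, 4342 and 1763 for strain after uninephrectomy, and 1563 and 340 for uninephrectomy in SBH/y. They were 79 and 1 for the interaction, 5763 and 36 for strain on average and 1404 and 4 for uninephrectomy on average. For the interaction, kidney number was shuffled within each strain. Those splits broke up the uninephrectomy response of both strains, so they do not test whether the strains responded alike.

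The stronger uninephrectomy response of SBH/y was set against 3 explanations. An effect of RNA degradation in proportion to the GAPDH measure is argued against by the group means of that measure. It rose no more in SBH/y (0.46 to 0.53 log2) than in SBN/y (0.35 to 0.45). So balanced a covariate could hardly move the interaction, so the fit with it adds little. In that fit the median ratio of the new to the old interaction was 1.004 (0.941 to 1.081) and 79 of 79 calls were kept. Degradation acting in another way was not tested. An effect of any 1 rat is argued against by the at least 52 of 79 calls kept with 1 array left out (52 without replicate 6 of SBN/y with 1 kidney). For 19 tubular injury genes, an effect of 1 or 2 rats with 1 kidney is argued against by the mean response of these genes. It was 0.427 to 0.873 in the 6 SBH/y rats with 1 kidney and 0.077 to 0.27 in the 6 SBN/y rats with 1 kidney. Each was taken against the mean of the strain's rats with 2 kidneys, so an effect of rats with 2 kidneys was not tested this way. No pair of arrays was left out, so an effect of 2 rats on the other calls was not tested. A larger share of myeloid cells as the whole cause stays open for both directions. Errors given here are SEs over genes or probe sets, so they do not measure the spread between rats. Dilution by such cells would lower all other transcripts alike. The 14 probe sets with a more negative response had a median interaction of -0.679 ± 0.071, with Cyp2c11 falling from 9.75 to 8.18 in SBH/y. The 16 proximal tubule genes had -0.063 ± 0.024, and intercalated cell genes, the lowest of 5 tubule lists, -0.179 ± 0.036. However, the 14 were picked for low values, so their lower median does not decide it. For the 65 with a more positive response, the median was 0.78, against 0.317 ± 0.052 for 16 myeloid genes, at most 0.487 for Cd68. These 65 were picked for large values, and the 19 tubular injury genes, fixed beforehand, had 0.393 ± 0.123. A strain difference in the response of the remaining kidney, which the design names, may underlie the pattern but was not tested apart from cell makeup.

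Large strain differences at single probe sets, such as those of RT1-Ba and RT1-Bb, may reflect sequence differences under the probes rather than transcript levels. Genes called at 0.5 log2 or more were examined if they had a second probe set above the median level of all probe sets. With 2 kidneys, 72 genes called between the strains met this. Their second probe set moved the same way for 66.7% and the opposite way for 8 (unadjusted limma p under 0.05). For uninephrectomy in SBH/y it moved the same way for 87.5% of 16 such genes (Fisher's exact p = 0.134, two-sided). With so few genes, sequence differences cannot be told apart from transcript change. Neighbouring genes were both called in 218 pairs of 13348, against 128 to 197 in 1000 shuffles (ratio to their mean 1.336, and 1.131 for uninephrectomy in SBH/y), which is consistent with stretches of the genome fixed differently in the strains. For strain after uninephrectomy the ratio was 1.17. Sequence differences under the probes would cluster along the genome as well, so this count does not choose between them.

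Clock genes that differed between the strains may reflect the time of day at which the kidneys were taken. Dbp and Bmal1 moved oppositely within groups too, with a Pearson r of -0.767 (permutation p = 0.00042) and a Spearman rho of -0.694 (permutation p = 0.00141) over 23 arrays after group means were removed, and r = -0.621 without the 2 farthest arrays. No time of day was known for these rats, so time of day and strain cannot be told apart for these genes. Sequence under the probes stays open as well, since 1 of 2 called clock genes with a bright second probe set moved the same way there, Nr1d2 (-1.087 and -0.976) but not Cry2 (-0.244 and 0.024). A strain difference in the clock itself was not tested. After uninephrectomy in SBH/y, 3 of 16 clock genes rose and 1 fell (5 and 3 adjusted over the list alone). Camera did not call that list (adjusted p = 0.977). The fry test found change in either direction (adjusted p = 3.39e-06), as it did for growth factor genes (fry adjusted p = 2.71e-14), which camera did not call either. For the response of clock genes such as Nr1d1, time of day and uninephrectomy cannot be told apart either.

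For 166 genes in 4 groups each, 1 rat lay far from the others of its group in 55 of 664 groups, where chance gives about 1 in 20, or 33.2. Replicate 4 of SBN/y with 1 kidney stood apart for 9 genes, high for Akr1b1 (9.14), Lpl (8.39), Nr1d1 (6.94), Csf1r (6.72), Mmp2 (6.45), Cd68 (5.70) and Klk1c4 (5.17) and low for Ly6i (8.31) and Gc (7.26). Replicate 3 of SBH/y with 2 kidneys stood low for 7 genes, Lpl (9.38), Eif2s3y (7.42), Pamr1 (7.26), Sfpq (6.49), Slc22a13 (6.42), Ces1e (4.52) and Mis18a (4.46). In SBH/y with 1 kidney, replicate 1 was high for Clu (10.54) and Timp1 (7.53) and low for Spp2 (10.72), Ugt2b7 (6.54) and Clic3 (5.21). Replicate 3 of that group was high for Cyp4a8 (12.002), Cyp4a1 (10.99), Tmem252 (10.64), Slc25a25 (8.94) and Nkd2 (6.003). Its replicate 5 was low for Mmp12 (5.39) and high for Scd (5.43), its replicate 6 low for Ces1e (4.20) and high for Cxcl10 (6.30), and its replicate 2 high for Casr (7.15). In SBH/y with 2 kidneys, replicate 1 was low for Ifi27 (9.50), Irf7 (6.85), Kl (5.15) and Tnfrsf12a (4.93), replicate 5 high for Col3a1 (8.39) and low for Thrsp (4.64), and replicate 6 high for Srsf5 (9.50) and low for Scd (3.85). In SBN/y with 1 kidney, replicate 3 was high for Egr1 (7.04), replicate 5 high for Mki67 (3.51) and replicate 6 low for Casr (7.73). In SBN/y with 2 kidneys, replicate 1 was high for Ccn2 (8.64) and Dph6 (8.34), and replicate 4 high for Pou2f1 (6.28) and low for Cys1 (7.08). Replicate 2 of that group was high for Casr (8.12) and Ube3al1 (6.68) and low for Srsf5 (9.35), Acadsb (5.81) and Lox (4.08), and replicate 3 was high for Aqp2 (10.84) and Dnase1 (10.70) and low for Cyp4a3 (12.02) and Hbb (11.56).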

How the results depend on the processing

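The tests with the GAPDH covariate and without the 3 arrays of smallest spread were chosen only after the data were seen. Counts of calls stayed within 1.5 times of those reported when arrays were quantile-normalized again (2983, 4544, 63, 1725 and 87 for strain with 2 kidneys, strain with 1, uninephrectomy in SBN/y, in SBH/y and the interaction), when dim probe sets were left out (2649, 4013, 78, 1635 and 93) and without the 3 arrays of smallest spread (2506, 4814, 38, 1591 and 98). A trended and robust variance gave 124 interaction calls. With only the groups compared in the fit, 2726 and 3861 calls were made for strain with 2 kidneys and with 1. For uninephrectomy that fit made 58 calls in SBN/y, with 33 of the 52 kept. In SBH/y it made 1055, of which 360 were downwards, with 1019 of the 1563 kept. With 1 probe set per gene, fewer features were tested and 1748, 2810 and 3584 genes passed for strain with 2 kidneys, with 1 and on average. The GAPDH covariate gave 124 interaction calls and 804 for uninephrectomy on average (401 upwards), and 62 for uninephrectomy in SBN/y, 27.4% of them higher against 50%. The cause was not tested. That fit kept 79 of 79 interaction calls, 646 of 1404 for uninephrectomy on average and 31 of 52 for uninephrectomy in SBN/y. For strain with 2 kidneys it made 2897 calls and kept 2207 of 2817. With 1 array left out, counts ranged from 2412 to 2747 for strain with 2 kidneys, 3713 to 4389 for strain with 1, 24 to 78 for uninephrectomy in SBN/y, 1057 to 1765 in SBH/y and 52 to 157 for the interaction, and on average from 5367 to 6013 for strain and 1126 to 1572 for uninephrectomy. Of 108 list calls, 32 held with an estimated correlation, 100 to 114 were made with 1 array left out, and fry made 122. The next probe set reversed RT1-Ba (-0.48 with 2 kidneys, -0.73 with 1), while the dim next probe sets of RT1-Bb with 2 kidneys (0.045, adjusted p = 0.821) and Prox1 in SBN/y (0.051, adjusted p = 0.982) showed no call in either direction. Of 112 calls of named genes, 2 ended with the trended variance, 6 with the replicate block, 7 with the GAPDH covariate and 7 without the 3 arrays, all for uninephrectomy in SBN/y except the interaction of Nr1d1 with the trended variance and without the 3 arrays. With a replicate block the 5 counts were 2718, 4302, 48, 1515 and 67, but the numbers did not pair the rats, since same-numbered arrays deviated together with a mean r of -0.021 to 0.103 and 2 of 23 arrays correlated best with their own number. Arrays give no count depth, and the median probe set had a mean of 4.662, below which signal over background limits what can be seen.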

Other observations

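None of the tests given here was chosen only after the result was seen. Single genes of vitamin D and mineral handling differed between the strains. The calcium-sensing receptor gene Casr was lower in SBH/y by -0.93 ± 0.08 (SE) log2 with 2 kidneys and by -1.08 ± 0.08 after uninephrectomy. Kl, which encodes klotho, was lower by -0.46 ± 0.12 and -0.68 ± 0.12, the calbindin gene Calb1 by -0.49 ± 0.13 and -0.52 ± 0.12, and the parathyroid hormone receptor gene Pth1r by -0.26 ± 0.06 and -0.19 ± 0.06. These 4 of 12 measured genes were lower in both comparisons (adjusted over the list alone, 4 lower and 2 higher with 2 kidneys, and 4 lower and 1 higher with 1). Cyp27b1, which makes the active form of vitamin D, was higher by 0.37 ± 0.11 with 1 kidney. Camera did not call the list with 2 kidneys (adjusted p = 0.106; adjusted p = 0.551 with an estimated correlation) or with 1 (adjusted p = 0.0827; adjusted p = 0.253 with an estimated correlation). Growth factor and hypertrophy genes went both ways with 1 kidney, 6 of 18 higher and 5 lower in SBH/y (6 and 5 adjusted over the list alone; camera adjusted p = 0.8), with Myc at 1.25 ± 0.11, Igf1 at 0.40 ± 0.07 and the growth hormone receptor gene Ghr at -0.35 ± 0.07. Glutathione genes did so as well, 5 of 21 higher and 9 lower (6 and 9 adjusted over the list alone; camera adjusted p = 0.0545), with Gstt2 at -0.99 ± 0.07 and Abcc2 at 0.60 ± 0.11.

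In SBH/y kidneys after uninephrectomy, the cathepsin genes Ctsl (0.35 ± 0.05) and Ctsb (0.21 ± 0.05) and the neonatal Fc receptor gene Fcgrt (0.23 ± 0.05) rose, 3 of 14 genes of protein endocytosis (3 adjusted over the list alone; camera adjusted p = 0.00983; adjusted p = 0.0803 with an estimated correlation). The adhesion molecule gene Icam1 (0.44 ± 0.07), the cytokine gene Il34 (0.42 ± 0.07) and Cxcl10 (0.52 ± 0.12) rose with Nfkb1, 4 of 17 inflammation genes (6 adjusted over the list alone; camera adjusted p = 0.00309; adjusted p = 0.0803 with an estimated correlation). Of 18 growth factor and hypertrophy genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.431; adjusted p = 0.52 with an estimated correlation). Myc rose by 0.93 ± 0.11 and the cell cycle inhibitor gene Cdkn1a by 0.43 ± 0.07, while Igfbp3 fell by 0.41 ± 0.07. None of 23 genes of oxidative phosphorylation passed the limma test in SBH/y (0 adjusted over the list alone), but the list moved downwards by a mean of -0.07 (camera adjusted p = 9.66e-05; adjusted p = 0.159 with an estimated correlation).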
